A study of Mus musculus with 54 samples.

How the data were processed

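The series holds 54 1-channel Affymetrix arrays of mouse mammary gland RNA, 3 mice at each of 18 time points, with 12488 probe sets per array. Per the submitters' processing notes, the deposited values are signal intensities computed by the authors with the MAS5 algorithm and scaled to a common level. The version of that software is not given in the sources used here. The values were checked to be on a linear scale, and the 2% trimmed mean of each array lay between 100.05 and 100.07. Time points were taken from the sample labels, and the letters A, B and C were treated as names of the 3 mice of a time point.

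Signals under 9.4, the 25th percentile of the table, were set to 9.4 and all values were taken to log2. The 66 control probe sets were left out, and a probe set was kept when its signal passed 22.8, the 40th percentile, in all 3 arrays of at least 1 time point, which left 8640. Of the non-control probe sets 10833 had exactly 1 gene symbol, 396 had several and 1193 had none. For 10817 of the single-symbol probe sets the Entrez identifier was in the reference table, and 0 symbols changed in the update. Where a gene had more than 1 kept probe set (1137 genes), the probe set with the highest mean log2 signal stood for it. This gave 7311 features, called genes here, of which 6441 had exactly 1 symbol and 870 did not.

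All 54 arrays were fitted together with limma 3.58.1 in R 4.3.3, with 1 mean per time point and an eBayes variance trend on intensity (36 residual and 6.77 prior degrees of freedom). Tests were two-sided, p values were adjusted by the Benjamini-Hochberg method over all features of a comparison, and a gene was called at an adjusted p under 0.05. The fit gave 8 comparisons of time points and an F test over the 18 time points. Standard errors pool the spread of all time points. For Csn2 the SD of log2 was 3.31 at virgin week 10, and for Wap it was 2.93 at pregnancy day 1, which widens the standard errors of these genes everywhere. Tables were handled and figures drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

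Named genes followed a rule with 3 parts, applied to each comparison. The first took the 8 genes with the largest rise and the 8 with the largest fall among called genes with exactly 1 symbol whose 3 + 3 arrays did not overlap. The second took up to 4 members, called ones first and then those with the largest change, from each fixed list that passed its test or had at least 3 called members. The third was a set of fixed genes: Csn2, Wap, Lalba, Krt8, Krt14, Adipoq, Stat3, Lbp, Cd14 and Igfbp5. Krt14 was too dim to pass the filter and Igfbp5 had no matched probe set, so neither was analysed here. The text gives a part of the genes the rule names. Glo1 and Cd79b levels, and the levels between comparisons, were looked at after the values were seen. The rule, the lists, the comparisons and the first set of alternative settings were fixed before the data were examined.

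There were 23 fixed lists, 12 of pathways and 11 of cell types, matched on current and older symbols. Those with at least 5 measured members, 22 lists, were tested in each comparison with camera (preset correlation 0.01), 176 tests adjusted together. The neutrophil list had 4 of 10 members measured and no test, with 1 member higher and 1 lower between the virgin ages, 0 higher and 1 lower at pregnancy day 14.5, and none called elsewhere. Members without a matched probe set in the tables used were not analysed here. Members too dim to pass the filter were Insig1, Bub1, Mcm6, Pgr, Ssr4, Calr, Slc7a1, Itih4, Tnfsf10, Il6, Mmp2, Adamts1, Mx1, Elovl3, Ppargc1a, Krt5, Krt14, Itgam, Fcer1g, S100a9, Ly6g, Mpo, Cxcr2, Ngp, Mmp8, Cr2, Cxcr5, Cd3d, Cd8a and Cd28.

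Alternative settings were no floor, a floor at the 40th percentile, quantile normalization, median scaling, no filter, all probe sets without collapsing, only the 6 arrays compared, no intensity trend, array quality weights, the letter as a replicate block, leaving out each array in turn, camera with an estimated correlation, and fry. The beta-actin 3' to 5' ratio, and the Arl2bp and Glo1 signals, were added as covariates after the data were seen. The pipeline was tested on simulated data with 7311 features and 100 changed genes per fold size in each comparison. It recovered 43% to 53% of 2-fold and 84% to 93% of 4-fold changes, and 2.82% to 9.03% of its calls were false. A shifted list was called in 8 of 8 comparisons, and 1 of 176 tests of unshifted lists was called. The simulated noise was independent between genes, the lists were random, and p values were adjusted within each comparison. The simulation therefore cannot show how often lists of genes that vary together are called falsely. Each simulated gene also had the same spread at every time point, as the fit assumes. The shares of recovered and false calls thus do not cover genes whose spread differs between time points.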

Results

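RNA from 54 mouse mammary glands was measured on 1-channel Affymetrix arrays, with 1 inguinal gland of 1 mouse per array and the lymph node removed. The glands fall into 18 time points of 3 mice each: virgin weeks 6, 10 and 12, pregnancy days 1, 2, 3, 8.5, 12.5, 14.5 and 17.5, lactation days 1, 3 and 7, and involution days 1, 2, 3, 4 and 20. Mice were mated at 12 weeks, and involution began when the pups were taken away after 7 days of lactation. Values are array signals, scaled so that the trimmed mean of each array lay between 100.05 and 100.07. Array medians ran from 31.8 to 44.6, and the highest signal was 17265.5. Between 20.5% and 29.7% of the probe sets of an array lay under the floor of 9.4. Arrays of the same time point correlated at r of 0.878 to 0.977 across genes, and for 38 of the 54 arrays the closest other array came from the same time point. The number of mice, 3 per time point, limits the precision of each value.

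Milk protein genes traced the cycle of the gland. Whey acidic protein (Wap) gave a mean signal of 9.4, the floor, at virgin week 6, 5150 at pregnancy day 14.5, 15400 at lactation day 7, 5480 at involution day 4 and 186 at involution day 20. Lalba, which encodes the alpha-lactalbumin needed to make lactose, had a mean of 13.5 at pregnancy day 12.5, 282 at day 14.5, 1040 at day 17.5 and 8490 at lactation day 1. Elf5, a transcription factor of the secretory epithelium, rose from 59.0 at virgin week 12 to 1770 at lactation day 7 and stood at 118 at involution day 20. Csn1s1, Csn1s2a, Csn1s2b, Csn2, Csn3, Wap, Lalba and Glycam1 together took up 0.0737% ± 0.0329 (SD, n = 3) of the summed signal at virgin week 6. Their share was 4.71% ± 0.0807 (SD, n = 3) at lactation day 7 and 0.641% ± 0.0823 (SD, n = 3) at involution day 20. Of 7311 genes tested, 6505 (89.0%) changed over the 18 time points. Among these, the highest mean fell at lactation day 7 for 1114 genes (17.1%), at virgin week 6 for 1036 (15.9%), at involution day 1 for 528 (8.12%) and at lactation day 3 for 511 (7.86%).

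**Figure D1:**
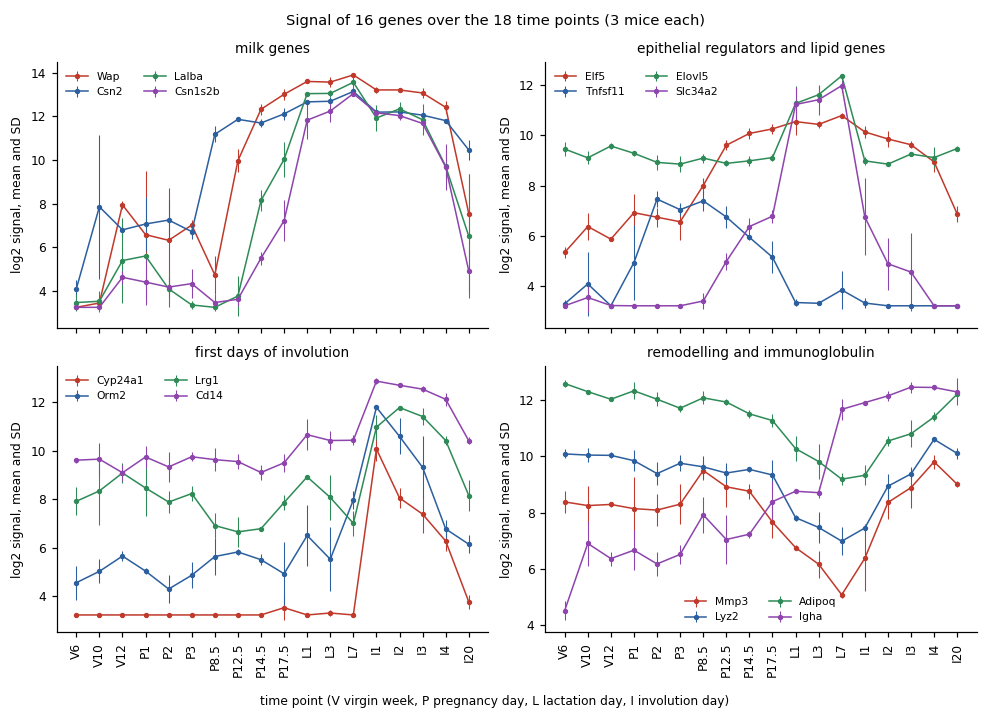
Mean log2 signal of 16 genes at the 18 time points, in time order along the x axis, with bars of 1 SD over 3 mice. Wap reaches a mean signal of 15400 at lactation day 7, and Cyp24a1 leaves the floor at involution day 1 with 1090.

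**Figure D2:**
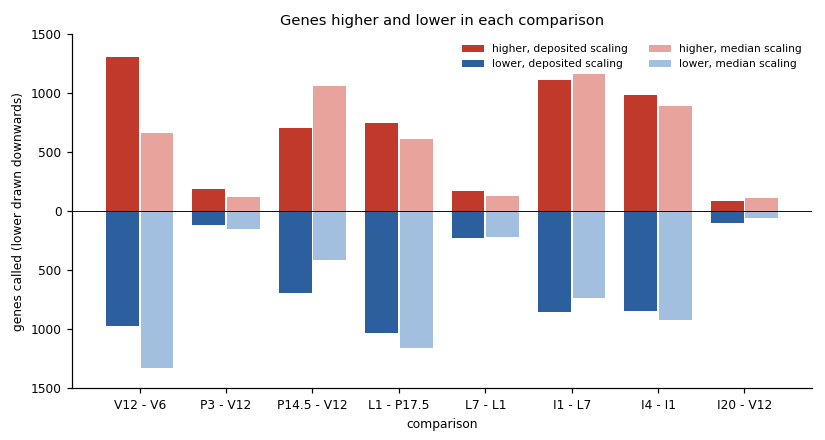
Number of genes called higher and lower in each of the 8 comparisons, with the deposited scaling and with each array scaled to the same median. The counts with the deposited scaling run from 189 (involution day 20 against virgin week 12) to 2278 (virgin week 12 against week 6), and the median scaling changes the share of higher genes most between the virgin ages, from 57.3% to 33.5%.

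Changes in 8 pairs of time points are described next, each as the log2 difference ± its standard error from the limma fit with n = 3 mice per time point, and with adjusted p values. Fixed lists of pathway genes and cell type markers were tested with camera. Of 176 list tests, 69 passed, and in each of these 69 the median, the mean and the direction of the test had the same sign. With a correlation estimated from the data, 15 of the 69 still passed. Scaling each array to the same median shifted the median of all genes by -0.22 between the virgin ages, by 0.19 at pregnancy day 14.5 and by 0.15 at involution day 20, and quantile normalization shifted it by -0.13 between the virgin ages. The acute phase list was written with knowledge of publications on this kind of gland series and is not independent evidence of direction.

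**Figure D3:**
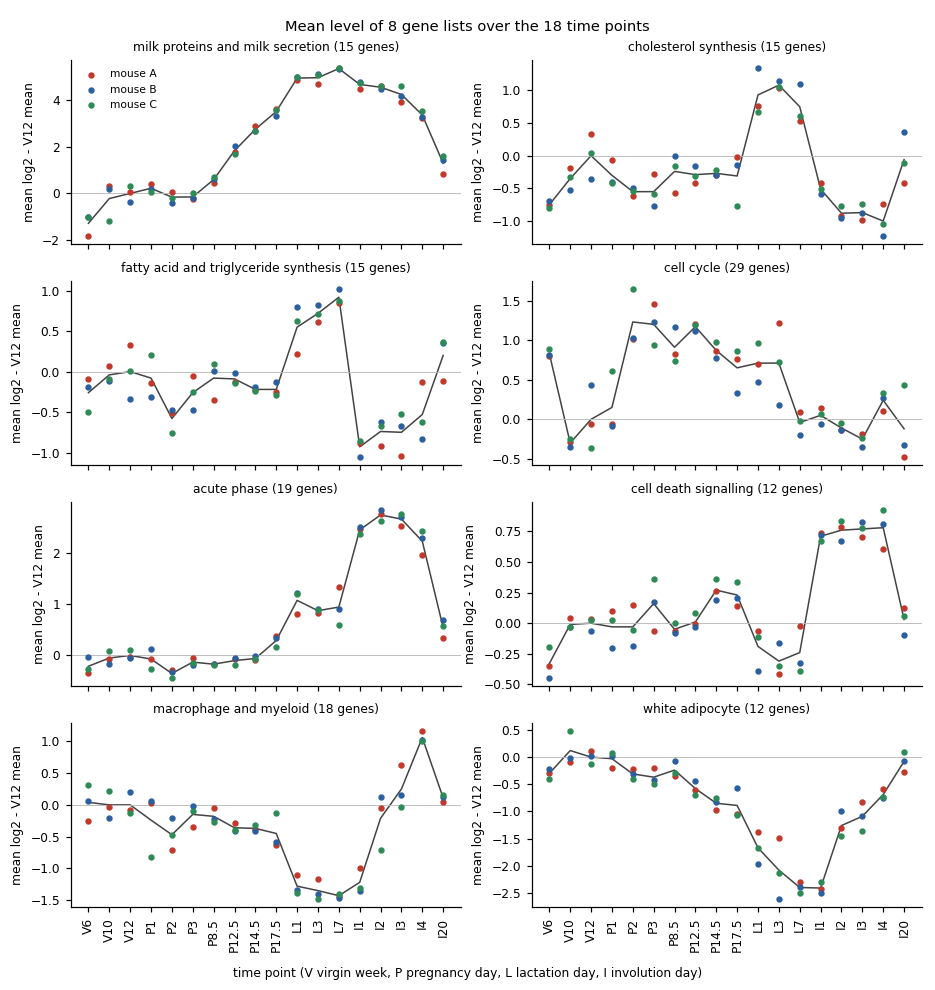
Mean log2 signal of 8 fixed gene lists relative to virgin week 12 at the 18 time points, with 1 point per mouse and a line through the means of 3 mice. The milk list stands 5.35 above virgin week 12 at lactation day 7, and the white adipocyte list 2.41 below it at involution day 1.

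The first comparison asked what changes in the virgin gland between 6 and 12 weeks of age. Milk protein genes were higher in the older gland. Wap rose from the floor to 246, at least 26.2-fold (adjusted p = 7.4e-05), and Csn2, the beta-casein gene, rose from 16.9 to 111 (2.71 ± 0.67, adjusted p = 0.0029). The luminal keratins rose as well, Krt18 from 263 to 718 (1.45 ± 0.31) and Krt8 from 325 to 816 (1.33 ± 0.32). Genes of dividing cells fell: Mad2l1, of the spindle checkpoint, from 144 to 26.8 (-2.43 ± 0.32, adjusted p = 6.1e-06), Ccnb2 from 436 to 106 (-2.04 ± 0.32) and Pcna from 585 to 163 (-1.84 ± 0.32). Other large rises were those of G0s2, an inhibitor of fat breakdown (6.98-fold), and Fcgbp, a mucus protein gene (5.38-fold). Adipoq, the adipocyte hormone adiponectin, had means of 6200 and 4210 and was not called (adjusted p = 0.051).

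By list, 8 of 15 milk genes rose and 0 fell from week 6 to week 12 (8 and 1 adjusted over the list alone, median 1.05, camera adjusted p = 0.0052, adjusted p = 0.24 with an estimated correlation). Of 15 luminal markers 9 rose and 0 fell (11 and 0 adjusted over the list alone, adjusted p = 0.0012, adjusted p = 0.19 with an estimated correlation). Cholesterol synthesis genes rose, 7 of 15 with 0 falling (8 and 0 adjusted over the list alone, adjusted p = 0.015, adjusted p = 0.37 with an estimated correlation), among them Mvk from 43.2 to 164. Of 29 cell cycle genes 12 fell and 1 rose (14 and 1 adjusted over the list alone, median -0.84, adjusted p = 5.7e-06, adjusted p = 0.22 with an estimated correlation). Fibroblast and matrix genes fell, 8 of 15 with 0 rising (9 and 0 adjusted over the list alone, adjusted p = 0.0004, adjusted p = 0.36 with an estimated correlation), such as Col5a2 (1200 against 2810) and Lum (1330 against 2670). The interferon list did not pass (adjusted p = 0.2, and 0.0258 downward with the beta-actin ratio as a covariate), with 2 of 13 members higher and 5 lower (3 and 6 adjusted over the list alone), Ifit1 at 29.3 against 124 and Ifit2 at 16.3 against 67.3.

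In all, 2278 genes (31.2%) differed between the virgin ages, 1306 higher and 972 lower at week 12. With each array scaled to the same median the split was 668 higher and 1329 lower, and with quantile normalization 1026 and 1048. The 3 + 3 arrays did not overlap for 3768 genes (51.5%), where chance gives 10%. The ratio of the 3' to the 5' beta-actin control probe sets, which reads RNA integrity and labelling, was 3.75 ± 0.363 (SD, n = 3) at week 6 and 1.99 ± 0.487 (SD, n = 3) at week 12. The mean Gapdh ratio of the same kind went the other way, 2.58 ± 0.46 (SD, n = 3) at week 6 and 3.95 ± 1.52 (SD, n = 3) at week 12. Week 12 mouse A, at 2.2, lay below every week 6 mouse, while mice B and C had 4.71 and 4.93. With the beta-actin ratio as a covariate 344 genes were called, the median size of the 2278 differences went from 0.95 to 0.58 with a median standard error of 0.302 against 0.294, and Krt8, Col5a2 and Lum no longer passed (adjusted p = 0.075, 0.15 and 0.097, with log2 differences of 0.96, -0.87 and -0.77), while Wap, Csn2, Krt18, Mvk, Mad2l1, Ccnb2 and Pcna did.

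Pregnancy day 3 was set against virgin week 12, the age at mating, to read the response early in pregnancy. Tnfsf11, which encodes the growth signal RANKL that progesterone induces in the gland, rose from the floor to 132, at least 14.1-fold (adjusted p = 1.6e-07). Rspo1, a secreted activator of Wnt signalling, rose from the floor to 61.0, at least 6.49-fold (adjusted p = 1.2e-07). Proliferation genes rose with them, Stmn1 from 132 to 628 (2.25 ± 0.32, adjusted p = 2.4e-05), Top2a from 11.7 to 59.8 (2.35 ± 0.46, adjusted p = 0.0017) and Prc1 from 16.9 to 87.7 (2.38 ± 0.54, adjusted p = 0.0068). Ly6d, a surface protein gene, fell from 360 to 50.9 (-2.82 ± 0.54, adjusted p = 0.0013), and Hoxd10 fell to the floor from 43.2, at least 4.59-fold lower. Csn2 (105 against 111) and Krt8 (812 against 816) were not called.

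In the cell cycle list at day 3, 12 of 29 members rose and 0 fell (15 and 0 adjusted over the list alone, median 1.09, adjusted p = 5.2e-16, adjusted p = 0.024 with an estimated correlation). In the steroid, prolactin and STAT5 list 3 of 11 rose and 0 fell (6 and 0 adjusted over the list alone, adjusted p = 0.00038, adjusted p = 0.026 with an estimated correlation), namely Tnfsf11, Wnt4 (81.5 against 27.4) and Socs2 (298 against 129). T cell markers fell, 2 of 7 with 0 rising (3 and 0 adjusted over the list alone, adjusted p = 0.00076, adjusted p = 0.25 with an estimated correlation), Cd3e to 14.8 from 68.7 and Cd5 to 11.2 from 41.1. Virgin week 12 had the highest Cd3e mean of all time points, against 36.5 at week 10. Pregnancy day 14.5 and involution day 20 were set against the same baseline, so their falls are not independent of this one. Cholesterol synthesis fell as a list with 1 of 15 members called lower (1 adjusted over the list alone, median -0.60, adjusted p = 0.0004, adjusted p = 0.18 with an estimated correlation). The list mean of day 3 mouse A (-0.277) lay above that of virgin mouse B (-0.362). Smaller shifts passed for fatty acid synthesis (2 lower, 3 adjusted over the list alone, adjusted p = 0.018), lysosome (1 and 2, 0.015), interferon (0 and 3, 0.014), white adipocyte (1 and 3, 0.014) and endothelial genes (0 and 1, 0.026). Brown adipocyte genes went down too, with 1 of 6 lower (3 lower and 1 higher adjusted over the list alone, adjusted p = 0.015, list mean -0.086 in mouse A against -1.262 in B and -0.95 in C). Basal markers went up with 0 of 10 called (1 higher adjusted over the list alone, adjusted p = 0.041). These 7 lists gave adjusted p = 0.42, 0.14, 0.4, 0.34, 0.24, 0.17 and 0.38 with an estimated correlation, in the order named. The basal call ended without a filter on dim probe sets (adjusted p = 0.0689) and with the beta-actin ratio (0.0592) or the Arl2bp and Glo1 signals (0.0958) as covariates, and the lysosome call with quantile normalization (0.0502) and with the Arl2bp and Glo1 signals (0.0706). The basal list mean was 0.428 without covariates, 0.424 with the beta-actin ratio and 0.336 with the Arl2bp and Glo1 signals. The lysosome mean was -0.201 without covariates and -0.152 with the Arl2bp and Glo1 signals. With fry the fatty acid, interferon and white adipocyte lists did not pass (0.16, 0.15 and 0.1).

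At day 3, 306 genes were called, 185 higher and 121 lower, and with median scaling 125 higher and 155 lower. For 2104 genes (28.8%) the arrays did not overlap, against 10% by chance. Wnt4 and Socs2 lost their calls without any 1 of the 6 arrays other than day 3 mouse A (adjusted p up to 0.18 and 0.15), Cd3e without any 1 of the 6 (up to 0.14) and Cd5 without virgin week 12 mouse B (0.077), and without a floor on low signals Wnt4 (0.166), Cd3e (0.0792) and Cd5 (0.261) did not pass. Top2a and Prc1 did not pass with the signals of Arl2bp and Glo1 as covariates (adjusted p = 0.081 and 0.1), nor did Wnt4, Socs2, Cd3e or Cd5, while Tnfsf11, Rspo1, Stmn1, Ly6d and Hoxd10 did. Top2a and Prc1 had log2 differences of 2.11 and 2.31 in that fit, whose median standard error was 0.359 against 0.294, and the median size of the called differences was 1.02 against 1.17.

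The mid pregnancy comparison, day 14.5 against virgin week 12, covers the growth of the lobules and alveoli. Fabp3, a fatty acid carrier, rose from 13.1 to 979 (6.22 ± 0.41, adjusted p = 1.4e-15). The caseins Csn1s2a and Csn2 rose, Csn1s2a from 81.5 to 4300 (52.7-fold) and Csn2 from 111 to 3330 (30.0-fold, adjusted p = 7.7e-07), and Wap rose from 246 to 5150 (20.9-fold). Elf5 rose from 59.0 to 1080 (4.20 ± 0.29, adjusted p = 5.8e-15). Pigr, the receptor that carries immunoglobulin A into milk, rose from 68.3 to 1320 (4.27 ± 0.24). The gap junction gene Gjb2 rose from 57.7 to 1780, and Gjb6, another, from the floor to 250, at least 26.6-fold.

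Falls at day 14.5 included Ly6d, from 360 to 10.1 (-5.16 ± 0.54), and Ucp1, the uncoupling protein of brown fat, from 136 to 10.4 (-3.71 ± 0.65, and -1.67 for its other probe set). Foxa1, a partner of the estrogen receptor in luminal cells, fell from 161 to 20.5 (-2.97 ± 0.40, adjusted p = 4.6e-07). Itih2, from a family of hyaluronan-binding plasma proteins, fell from 99.4 to the floor, at least 10.6-fold lower. Arl2bp, a binding partner of a small GTPase, fell from 692 to 76.3 (-3.18 ± 0.60), in the manner described after the comparisons. Adipoq (2930 against 4210) was not called.

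As groups, 11 of 15 milk genes rose and 0 fell (13 and 0 adjusted over the list alone, median 2.76, adjusted p = 4.4e-13, adjusted p = 0.008 with an estimated correlation). Cell cycle genes were still high, 12 of 29 up and 1 down (14 and 1 adjusted over the list alone, adjusted p = 4.5e-06, adjusted p = 0.22 with an estimated correlation), Stmn1 at 764 against 132. The steroid, prolactin and STAT5 list had 5 of 11 up and 1 down (5 and 1 adjusted over the list alone, adjusted p = 0.00094, adjusted p = 0.041 with an estimated correlation). Basal and myoepithelial markers rose, 5 of 10 with 0 falling (6 and 0 adjusted over the list alone, median 1.02, adjusted p = 0.00023, adjusted p = 0.12 with an estimated correlation), such as Acta2 (1010 against 316) and Mylk (1060 against 411). Fat genes fell: 7 of 12 white adipocyte genes (9 adjusted over the list alone, adjusted p = 0.0012, adjusted p = 0.19 with an estimated correlation), with Lipe at 373 against 1160 and Cidec at 271 against 965, and 4 of 6 brown adipocyte genes (4 adjusted over the list alone, adjusted p = 0.0052, adjusted p = 0.12 with an estimated correlation).

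At day 14.5 the macrophage list did not pass (adjusted p = 0.18), and other lists of blood, vessel and stromal cells fell. T cell markers fell, 5 of 7 with 0 rising (5 adjusted over the list alone, median -1.86, adjusted p = 0.0039, adjusted p = 0.34 with an estimated correlation), Cd3e to 10.7 from 68.7. B and plasma cell markers fell, 4 of 9 (5 adjusted over the list alone, adjusted p = 0.015, adjusted p = 0.4 with an estimated correlation), Cd79b to 14.6 from 113. The baseline, virgin week 12, had the highest Cd3e and Cd79b means of all time points. Of 10 endothelial genes 5 fell (6 adjusted over the list alone, adjusted p = 0.015, adjusted p = 0.19 with an estimated correlation), with Kdr at 43.2 against 99.9, and of 15 fibroblast genes 3 fell (3 adjusted over the list alone, adjusted p = 0.022, adjusted p = 0.62 with an estimated correlation, 0.068 with fry). Acute phase genes went both ways, 4 of 19 up and 5 down: Lbp rose from 142 to 298, and Lrg1 and Hp fell from 545 to 110 and from 904 to 279. That list did not pass (adjusted p = 0.86), and its median of -0.23 and mean of -0.06 had the opposite sign to its test.

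Mid pregnancy gave 1402 called genes, 706 higher and 696 lower, with median scaling 1062 higher and 411 lower, and with array weights 1287 and 1503. The arrays did not overlap for 3560 genes (48.7%), against 10% by chance. With the Arl2bp and Glo1 signals as covariates Acta2 (adjusted p = 0.2), Cd3e (0.089), Kdr (0.35), Hp (0.056) and Lbp (0.33) did not pass, and the list of B and plasma cell markers did not pass either (0.0835, and 0.0523 with a floor at the 40th percentile). With the covariates the mean of that list was -1.14 against -1.188 without them. In the covariate fit Acta2 had 1.30, Cd3e -3.03, Kdr -0.79, Hp -1.97 and Lbp 0.65, with a median standard error of 0.468 against 0.294 and a median size of the called differences of 0.93 against 1.03. Changes predicted from the beta-actin ratio (2.74 against 1.99) correlated with the observed ones at r = 0.31 across genes.

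At the onset of lactation, day 1 was set against pregnancy day 17.5, the last time point before birth. The comparison spans birth as well as the start of secretion and cannot tell their effects apart. Saa2, a serum amyloid A gene, rose from 70.6 to 3110 (5.46 ± 0.59, adjusted p = 8.4e-09), with 3.20 for its other probe set. Cidea, a lipid droplet protein of fat and of milk-secreting cells, rose from 183 to 4860 (4.73 ± 0.32, adjusted p = 1.1e-14). The casein gene Csn1s2b rose from 148 to 3650 (4.62 ± 0.44), and Lalba from 1040 to 8490 (3.02 ± 0.72, adjusted p = 0.0017). The phosphate carrier Slc34a2 rose from 111 to 2400 (4.44 ± 0.50) and the calcium pump Atp2b2 from the floor to 97.0, at least 10.3-fold. Egf, the epidermal growth factor gene, rose 13.6-fold to 324, and Elovl5, which lengthens fatty acids, rose from 556 to 2460 (2.15 ± 0.21). Wap (12500 against 8300, adjusted p = 0.62) and Csn2 (6520 against 4450, adjusted p = 0.58), already high in late pregnancy, were not called.

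The steroid, prolactin and STAT5 list did not pass at lactation day 1 (2 of 11 up and 3 down, adjusted p = 0.84). Among single genes, Cyp1b1, which oxidises estrogens, fell from 156 to the floor, at least 16.6-fold lower, and Wnt4, a progesterone target, from 62.9 to the floor, at least 6.69-fold lower. Rspo1 fell from 166 to 11.2 (-3.88 ± 0.30, adjusted p = 6e-13). The metallothionein gene Mt2 fell from 2400 to 168 (-3.84 ± 0.52), the receptor gene Kit from 153 to 17 (-3.16 ± 0.39) and Phlda1 from 779 to 46.9 (-4.05 ± 0.36).

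Synthesis and export genes rose as groups at lactation day 1. Cholesterol synthesis had 12 of 15 up and 0 down (12 and 0 adjusted over the list alone, median 1.26, adjusted p = 6.4e-08, adjusted p = 0.037 with an estimated correlation), with Fdps at 1950 against 411 and Sqle at 437 against 127. Milk genes had 7 of 15 up and 0 down (7 and 0 adjusted over the list alone, adjusted p = 2.5e-06, adjusted p = 0.041 with an estimated correlation), with Muc1 at 4410 against 767. Transport genes had 7 of 13 up and 1 down (7 and 1 adjusted over the list alone, adjusted p = 0.00033, adjusted p = 0.041 with an estimated correlation), with the glucose carrier Slc2a1 at 206 against 47.0. Fatty acid synthesis had 8 of 15 up and 1 down (8 and 1 adjusted over the list alone, adjusted p = 0.00026, adjusted p = 0.19 with an estimated correlation), and the secretory pathway 10 of 17 up and 0 down (14 and 0 adjusted over the list alone, adjusted p = 3.8e-05, adjusted p = 0.12 with an estimated correlation). The acute phase list had 7 of 19 up and 1 down (7 and 1 adjusted over the list alone, median 0.11, mean 0.77, adjusted p = 0.0052, adjusted p = 0.12 with an estimated correlation), with Lbp at 1430 against 369 and Cd14 at 1630 against 730.

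At lactation day 1, 4 lists of stromal and immune genes fell, while the T cell, B and plasma cell and endothelial lists did not pass (adjusted p = 0.583, 0.49 and 0.496). Fibroblast and matrix genes had 10 of 15 down and 0 up (12 and 0 adjusted over the list alone, median -0.91, adjusted p = 0.00021, adjusted p = 0.34 with an estimated correlation). Macrophage markers had 9 of 18 down and 0 up (13 and 0 adjusted over the list alone, adjusted p = 0.00053, adjusted p = 0.24 with an estimated correlation), Lyz2 at 226 against 646. White adipocyte genes had 8 of 12 down (8 adjusted over the list alone, adjusted p = 0.0023, adjusted p = 0.22 with an estimated correlation), Adipoq at 1240 against 2490. Interferon-stimulated genes had 5 of 13 down (5 adjusted over the list alone, adjusted p = 0.0015, adjusted p = 0.28 with an estimated correlation), Psmb8 at 386 against 1190. In total 1783 genes were called at the onset of lactation, 747 higher and 1036 lower, and for 2688 (36.8%) the arrays did not overlap, against 10% by chance. The beta-actin ratio was 1.6 at lactation day 1 and 2.25 at pregnancy day 17.5, and changes predicted from it correlated with the observed ones at r = 0.28 across genes.

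Lactation day 7 against day 1 showed how the secreting gland goes on changing. Pip, which encodes the prolactin-induced protein of milk and saliva, rose from 23.4 to 409 (4.13 ± 0.42, adjusted p = 4.1e-09). Igha, the heavy chain of immunoglobulin A, rose from 435 to 3280 (2.91 ± 0.36, adjusted p = 4.9e-07), with rises of 0.66 to 2.91 over its 3 probe sets. Jchain, which joins immunoglobulin A units for transport into milk, rose from 93.0 to 340 (1.87 ± 0.39, adjusted p = 0.0018). Elovl5 rose further, from 2460 to 5290 (1.10 ± 0.21), and the fatty acid carrier Slc27a3 rose from 15.7 to 84.8 (2.43 ± 0.22). Fam3c, a secreted factor, fell from 185 to 14.5 (-3.67 ± 0.38, adjusted p = 9.1e-09), with -3.67 to -1.27 over its 3 probe sets, of which 2 were called, and Lamb3, a basement membrane laminin, from 312 to 38.2 (-3.03 ± 0.45, and -1.85 for its other probe set). Wap (15400 against 12500), Csn2 (9070 against 6520) and Lalba (12200 against 8490) were not called.

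Most lists that moved during lactation moved down. Fibroblast and matrix genes had 6 of 15 down (9 adjusted over the list alone, median -0.83, adjusted p = 6.6e-09, adjusted p = 0.12 with an estimated correlation), Col1a1 at 325 against 984. White adipocyte genes had 4 of 12 down (7 adjusted over the list alone, adjusted p = 0.00013, adjusted p = 0.12 with an estimated correlation), Adipoq at 583 against 1240. Cell cycle genes had 3 of 29 down (9 adjusted over the list alone, adjusted p = 1.4e-06, adjusted p = 0.19 with an estimated correlation), Rrm1 at 11.5 against 63.3. Interferon-stimulated genes had 3 of 13 down (7 adjusted over the list alone, adjusted p = 0.0004, adjusted p = 0.22 with an estimated correlation), and the secretory pathway 3 of 17 (6 adjusted over the list alone, adjusted p = 0.00023, adjusted p = 0.17 with an estimated correlation), Rpn2 at 352 against 656. Up went fatty acid synthesis, 1 of 15 (2 adjusted over the list alone, adjusted p = 0.0032, adjusted p = 0.31 with an estimated correlation), and the B and plasma cell list, 1 of 9 (2 adjusted over the list alone, adjusted p = 0.0062, adjusted p = 0.35 with an estimated correlation). Between these days 396 genes were called, 172 higher and 224 lower. The balance turned without a filter on dim probe sets (282 higher and 238 lower), with a floor at the 40th percentile (277 and 231) and with only the 6 arrays compared (32 and 24). For 1699 genes (23.2%) the arrays did not overlap, against 10% by chance.

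The first day of involution, 1 day after the pups were removed, was set against lactation day 7. Cyp24a1, which breaks down active vitamin D, rose from the floor to 1090, at least 115-fold (adjusted p = 1.2e-23). A second Cyp24a1 probe set was called in the opposite direction, with -0.73. Rnase1 rose from the floor to 597, at least 63.5-fold (adjusted p = 7.2e-19), and Pdk4, a brake on the use of glucose, rose from 37.5 to 1080 (4.85 ± 0.48). Cpt1a, which takes fatty acids into mitochondria for burning, rose from 25.8 to 474 (4.20 ± 0.31). Wfdc12, a protease inhibitor gene, rose from 14.8 to 2270 (7.26 ± 0.97), with 0.19 for its other probe set, and the 4 probe sets of its relative Slpi ran from -0.40 to 4.56. Kit rose from 11.9 to 259 (4.44 ± 0.39).

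Acute phase genes rose on the first day of involution, 11 of 19 with 2 falling (11 and 2 adjusted over the list alone, median 1.87, adjusted p = 2.4e-06, adjusted p = 0.0085 with an estimated correlation). Lrg1 rose from 129 to 2010 (3.97 ± 0.47, adjusted p = 7.9e-09), the orosomucoid gene Orm2 from 253 to 3550 (3.81 ± 0.56), the endotoxin receptor Cd14 from 1390 to 7560 (2.45 ± 0.29) and its partner Lbp from 1050 to 3840 (1.87 ± 0.22). Osmr, the oncostatin M receptor, rose from 21.2 to 187, and Stat3, which these receptors activate, from 349 to 683 (0.97 ± 0.24, adjusted p = 0.0021). Cell death signalling rose, 7 of 12 with 0 falling (8 and 0 adjusted over the list alone, median 1.04, adjusted p = 0.0016, adjusted p = 0.015 with an estimated correlation), with Tgfb3 at 688 against 186 and Pik3r1 at 415 against 71.0. Other rises were those of the luminal list (7 of 15 up and 1 down, 9 and 1 adjusted over the list alone, adjusted p = 0.016), with Cldn4 at 561 against 47.5, fibroblast genes (8 and 0, 8 and 0, 0.0022), with Col5a2 at 177 against 38.5, interferon-stimulated genes (5 and 1, 8 and 1, 0.0052), with Gbp2 at 104 against 28.3, and lysosomal genes (5 and 1, 5 and 1, 0.023), with Ctsl at 2720 against 932. These 4 lists gave adjusted p = 0.35, 0.44, 0.35 and 0.17 with an estimated correlation, in the order named.

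Synthesis and transport fell on the same day. Slc34a2 fell from 4050 to 109 (-5.22 ± 0.50, adjusted p = 4.2e-11) and Atp2b2 from 174 to 10.7 (-4.02 ± 0.28). Elovl5 fell from 5290 to 507 (-3.38 ± 0.21, adjusted p = 4.4e-16), and the desaturase Fads1 from 3350 to 477 (-2.81 ± 0.20). Fatty acid synthesis had 13 of 15 down and 0 up (13 and 0 adjusted over the list alone, median -2.02, adjusted p = 5.2e-14, adjusted p = 0.0085 with an estimated correlation). Cholesterol synthesis had 9 of 15 down and 0 up (11 and 0 adjusted over the list alone, adjusted p = 6.7e-06, adjusted p = 0.097 with an estimated correlation), with Mvd at 21.4 against 207. Transport had 6 of 13 down and 3 up (6 and 3 adjusted over the list alone, adjusted p = 0.012, adjusted p = 0.17 with an estimated correlation), the steroid, prolactin and STAT5 list 4 of 11 down (5 adjusted over the list alone, adjusted p = 0.01, adjusted p = 0.12 with an estimated correlation), with Stat5b at 21.2 against 115, and the secretory pathway 5 of 17 down and 1 up (8 and 1 adjusted over the list alone, adjusted p = 0.041, adjusted p = 0.46 with an estimated correlation). The secretory call ended with a floor at the 40th percentile (0.0643) and with the Arl2bp and Glo1 signals as covariates (0.0607, list mean -0.367 against -0.399 without them). The milk list did not pass (adjusted p = 0.058, 1 up and 1 down) but passed as a fall with fry (0.018), with median scaling (0.0497) and with the beta-actin ratio as a covariate (0.0348). It did not pass with an estimated correlation (0.437) or with the Arl2bp and Glo1 signals as covariates (0.0958). Over the planned changes of scaling, floor and filter its adjusted p reached 0.795, so the call depended on the setting. Csn2 (4720 against 9070), Wap (9560 against 15400) and Lalba (3910 against 12200) were not called. Their standard errors pool the spread of all time points, which was wide for Csn2 and Wap at early ones. A missing call is thus not evidence of an unchanged level. The milk protein genes summed above took up 2.81% ± 0.28 (SD, n = 3) of the signal at involution day 1. At lactation day 7 their share was 4.71% ± 0.0807 (SD, n = 3). The first day of involution gave 1969 called genes, 1114 higher and 855 lower, and for 3011 (41.2%) the arrays did not overlap, against 10% by chance. Changes predicted from the beta-actin ratio (2.09 against 1.82) correlated with the observed ones at r = 0.24.

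Genes switched at the onset of lactation were compared with those switched on the first day of involution, which share no array. Of 747 genes higher at the onset, 329 (44.0%) were lower at involution day 1, where 87.4 would fall by chance (odds ratio 9.03, 95% interval 7.59 to 10.7, Fisher's exact test, two-sided p = 1.7e-129). Of 1036 genes lower at the onset, 470 (45.4%) were higher at involution day 1, against 158 by chance (odds ratio 7.26, interval 6.25 to 8.43, Fisher's exact test, two-sided p = 8e-146). Genes that moved in the same direction both times numbered 18 up and 20 down, against 114 and 121 by chance. Slc34a2, Atp2b2, Egf and Elovl5 belong to the first set, and Kit to the second. Fisher's test takes genes as independent, so its p values and intervals describe the overlap across genes and not the spread between mice. The log2 beta-actin ratio also moved in opposite directions, by -0.48 at the onset and 0.19 at involution day 1. Its part in the overlap was not tested.

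**Figure D4:**
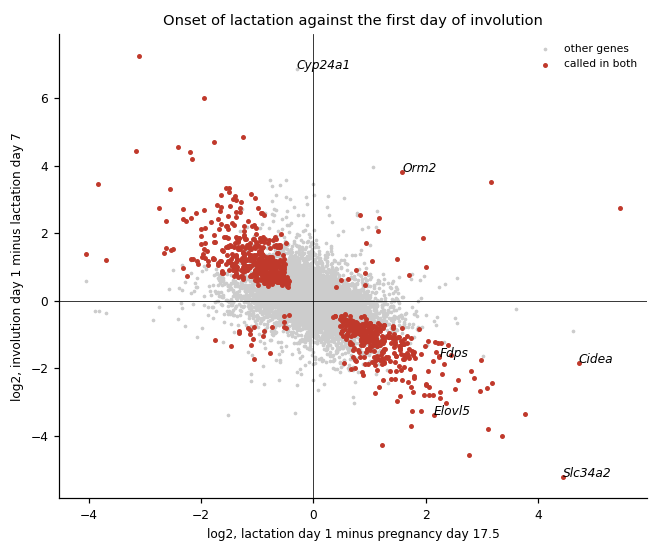
Log2 change of each tested gene at the onset of lactation (x axis) against its log2 change on the first day of involution (y axis), with genes called both times in red. Of the red genes 799 lie in the quadrants of opposite direction, such as Elovl5 (2.15 and -3.38), and 38 in those of the same direction.

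Involution day 4 against day 1 covers the turn to tissue remodelling. Hp, the haptoglobin gene, rose from 162 to 3610 (4.48 ± 0.39, adjusted p = 7.1e-12). Genes of macrophages rose, Lgals3 from 28.3 to 545 (4.27 ± 0.40), Tyrobp from 86.4 to 1030 (3.58 ± 0.31) and Lyz2 from 175 to 1570 (3.17 ± 0.26, adjusted p = 1.5e-12). Matrix proteases rose, stromelysin Mmp3 from 82.8 to 896 (3.44 ± 0.45) and the macrophage elastase Mmp12 from 84.6 to 830 (3.29 ± 0.68). Adipoq rose from 645 to 2720 (2.07 ± 0.22, adjusted p = 1.9e-09) and the lipid droplet gene Cidec from 40.3 to 597 (3.89 ± 0.40). Glycam1, a milk mucin, fell from 7700 to 155 (-5.64 ± 0.97, adjusted p = 2.2e-05), Fabp3 from 809 to 30.8 (-4.71 ± 0.41) and Csn1s2b from 4590 to 822 (-2.48 ± 0.44). Orm2 and Cyp24a1, which had risen on day 1, fell again, Orm2 from 3550 to 110 (-5.01 ± 0.56) and Cyp24a1 from 1090 to 77.6 (-3.81 ± 0.27). Wap (5480 against 9560) and Csn2 (3580 against 4720) were not called.

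Among the lists, 15 of 18 macrophage markers rose and 0 fell (15 and 0 adjusted over the list alone, median 2.49, adjusted p = 8.1e-17, adjusted p = 0.0083 with an estimated correlation). White adipocyte genes had 11 of 12 up (11 adjusted over the list alone, median 1.78, adjusted p = 1.4e-09, adjusted p = 0.015 with an estimated correlation), and matrix proteases and inhibitors 8 of 12 up and 0 down (9 and 1 adjusted over the list alone, adjusted p = 0.00042, adjusted p = 0.013 with an estimated correlation). Fibroblast genes had 12 of 15 up (13 adjusted over the list alone, adjusted p = 1e-08, adjusted p = 0.13 with an estimated correlation), Col3a1 at 1410 against 233. Endothelial genes had 6 of 10 up (6 adjusted over the list alone, adjusted p = 0.00051, adjusted p = 0.057 with an estimated correlation), Eng at 794 against 283. Lysosomal genes had 6 of 15 up and 3 down (7 and 3 adjusted over the list alone, adjusted p = 0.0076, adjusted p = 0.12 with an estimated correlation), Lgmn at 534 against 72.8. Milk genes had 7 of 15 down (7 adjusted over the list alone, adjusted p = 0.0012, adjusted p = 0.18 with an estimated correlation), basal markers 6 of 10 down and 0 up (6 and 1 adjusted over the list alone, adjusted p = 0.017, adjusted p = 0.32 with an estimated correlation), and cholesterol synthesis 5 of 15 down (5 adjusted over the list alone, adjusted p = 0.043, adjusted p = 0.46 with an estimated correlation). The basal call ended without a filter on dim probe sets (0.0743), and the cholesterol call with a floor at the 40th percentile (0.117) and with the Arl2bp and Glo1 signals as covariates (0.0607, list mean -0.457 against -0.496 without them). The acute phase list, with 5 of 19 up and 7 down (6 and 8 adjusted over the list alone), did not pass (adjusted p = 0.47).

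Later involution gave 1832 called genes, 987 higher and 845 lower, with median scaling 894 and 925, and for 3106 (42.5%) the arrays did not overlap, against 10% by chance. Skeletal muscle genes had 4 of 12 up (6 adjusted over the list alone, adjusted p = 0.014, adjusted p = 0.66 with an estimated correlation, 0.099 with fry), but their level varied within time points. Acta1, a muscle actin, ran from 12.8 to 107.3 over the 3 mice at involution day 1 and from 286.8 to 1341.2 at day 4, and its call ended without day 4 mouse A or C or day 1 mouse A or C (adjusted p up to 0.084).

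Involution day 20 against virgin week 12 asks how far the gland returns to its state before pregnancy. The day 20 mice, mated at 12 weeks, were also older, and no virgin mice of their age were measured. Age and the cycle thus cannot be told apart in this comparison. Over the virgin ages Igha had means of 22.7, 120 and 82.3 at weeks 6, 10 and 12. Igha stood at 5040 against 82.3 (5.94 ± 0.36, 61.2-fold, adjusted p = 1.8e-16), with 1.40 to 5.94 over its 3 probe sets, and Jchain at 1020 against 77.7 (3.71 ± 0.39, adjusted p = 9.4e-09). Higher too were the caseins Csn1s1, at 5320 against 209 (4.67 ± 0.96, adjusted p = 0.002), and Csn2, at 1410 against 111 (3.67 ± 0.67, adjusted p = 0.00038), and the milk fat globule gene Btn1a1, at 493 against 39.4 (3.65 ± 0.37, adjusted p = 6.5e-09). Mmp12 stood at 364 against 18.5 (4.30 ± 0.68), and Cck, the cholecystokinin gene, at 185 against the floor, at least 19.7-fold higher. Lower than in the virgin gland were Itih2 (9.43 against 99.4, -3.40 ± 0.55), Arl2bp (98.3 against 692) and Pik3cd, a kinase subunit of white blood cells (floor against 59.3, at least 6.31-fold lower). Wap (186 against 246), Adipoq (4760 against 4210) and Krt8 (532 against 816) were not called.

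As lists, milk genes were higher at day 20, 6 of 15 up and 1 down (7 and 2 adjusted over the list alone, median 0.63, adjusted p = 2.1e-08, adjusted p = 0.016 with an estimated correlation). Acute phase genes had 4 of 19 up and 0 down (7 and 0 adjusted over the list alone, adjusted p = 3e-05, adjusted p = 0.015 with an estimated correlation), with Lcn2 at 1350 against 358 (1.91 ± 0.28, and -0.09 for its other probe set), Cd14 at 1370 against 549 and Lbp at 313 against 142. T cell markers had 2 of 7 down (3 adjusted over the list alone, median -0.98, adjusted p = 0.0022, adjusted p = 0.32 with an estimated correlation), Cd3e and Cd5. Mouse A stood apart on that list, with a mean of -0.302 against -1.959 in B and -1.641 in C. The baseline was again virgin week 12, which had the highest Cd3e mean of all time points. Luminal markers went down as a list with 0 of 15 called (1 up and 2 down adjusted over the list alone, adjusted p = 0.0035, adjusted p = 0.24 with an estimated correlation), and skeletal muscle went up with 0 of 12 called (0 adjusted over the list alone, adjusted p = 0.049, adjusted p = 0.74 with an estimated correlation), Acta1 running from 418.3 to 1671.8 over the 3 mice. The skeletal muscle call at day 20 ended with quantile normalization (adjusted p = 0.0902), median scaling (0.151), fry (0.52) and the Arl2bp and Glo1 signals as covariates (0.0589, list mean 1.129 against 0.882 without them).

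At day 20, 189 genes were called, 87 higher and 102 lower, with median scaling 111 higher and 54 lower, and with quantile normalization 112 and 99. For 1819 genes (24.9%) the arrays did not overlap, against 10% by chance. Cd3e lost its call without day 20 mouse B or C or virgin week 12 mouse A or B (adjusted p up to 0.11), and Cd5 without day 20 mouse B or C or virgin week 12 mouse B (up to 0.22). With the Arl2bp and Glo1 signals as covariates Csn1s1 (adjusted p = 0.35), Csn2 (0.083), Lcn2 (0.17), Cd14 (0.35), Lbp (0.57), Pik3cd (0.35), Cd3e (0.38) and Cd5 (0.33) did not pass, while Igha, Jchain, Btn1a1, Mmp12, Cck and Itih2 did. In that fit Csn1s1 had 4.21, Csn2 4.13, Lcn2 1.51, Cd14 1.27, Lbp 0.63, Pik3cd -2.36, Cd3e -2.59 and Cd5 -1.90, with a median standard error of 0.48 against 0.294 and a median size of the called differences of 1.55 against 1.52. Changes predicted from the beta-actin ratio (2.57 against 1.99) correlated with the observed ones at r = 0.39 across genes.

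Arl2bp, named by rule in the mid pregnancy and day 20 comparisons, did not vary in steps of time alone. Its signal lay between 63.2 and 108.8 in 29 arrays and between 410.6 and 804 in the other 25, with no array in between. The 18 arrays from virgin week 6 to pregnancy day 3 were all at the higher level. Days 8.5 and 17.5 of pregnancy, days 1 and 3 of lactation and day 3 of involution held both levels, and the remaining time points held the lower level alone. Comparisons of pregnancy day 14.5 or involution day 20 with virgin week 12 thus set arrays of 1 Arl2bp level against arrays of the other. Pregnancy day 3 shares the Arl2bp level of virgin week 12, but its Glo1 mean was 224 against 387.

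**Figure D5:**
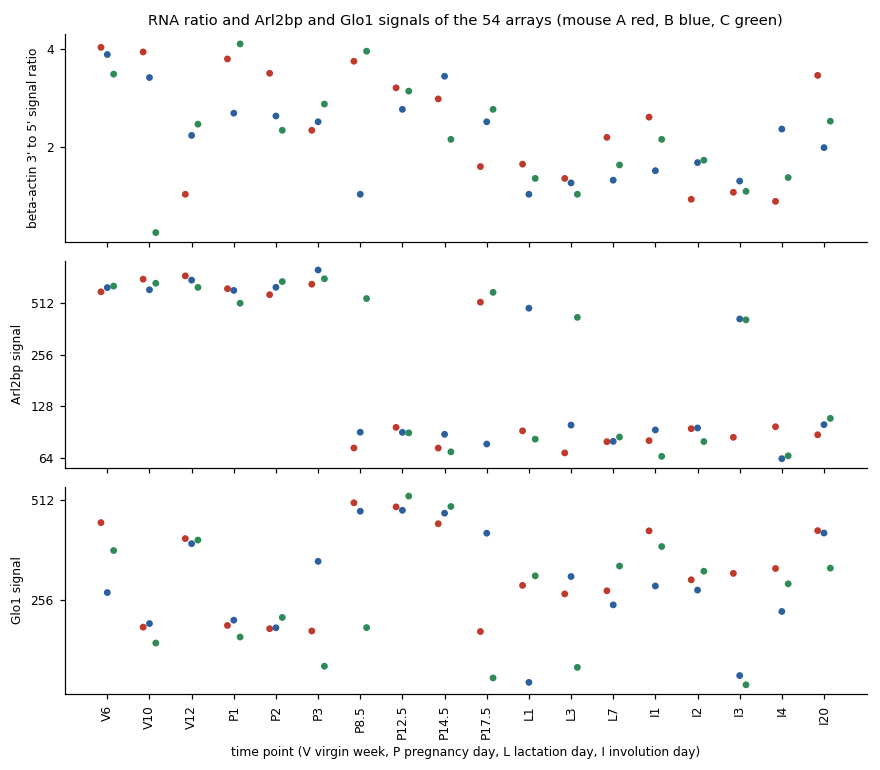
Ratio of the 3' to the 5' beta-actin control probe sets and signals of Arl2bp and Glo1 in each of the 54 arrays by time point, on log2 axes. The beta-actin ratio has its highest mean, 3.75, at virgin week 6, and Arl2bp lies at or under 108.8 in 29 arrays and at or above 410.6 in 25.

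Single arrays moved some counts by more than 1.5 times. The virgin comparison called 1414 genes without week 6 mouse A. Pregnancy day 3 called 105 without its mouse C, 116 without its mouse B and 143, 155 and 150 without virgin week 12 mouse A, B and C. Pregnancy day 14.5 called 836 without its mouse B, lactation day 1 called 954 without its mouse B, and lactation day 7 called 203 without day 1 mouse A and 252 without day 7 mouse C. Involution day 20 called 111, 110 and 118 without virgin week 12 mouse A, B and C.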

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

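The covariates described here were chosen after seeing the data, and the other alternatives were planned. Over the planned changes of floor, scaling, filter, trend and array weights, 426 to 454 calls of named genes kept their direction and significance and 7 to 35 lost it, and none reversed. Leaving out single arrays kept 2316 and lost 450, the beta-actin covariate kept 402 and lost 59, and the Arl2bp and Glo1 covariates kept 364, lost 94 and reversed 1. With only the 6 arrays compared, the spread was estimated from those arrays alone. The count then rose to 2374 at pregnancy day 14.5, against 1402 in the fit of all arrays. It fell to 707 at lactation day 1 (from 1783), 56 at lactation day 7 (from 396) and 99 at involution day 20 (from 189). The smaller number of arrays does not by itself account for moves in both directions. Array weights, from 0.17 to 7.29, gave 830 at pregnancy day 3, 2790 at day 14.5, 2762 at involution day 4 and 575 at day 20. Of the 69 list calls 15 passed with an estimated correlation, 63 with fry (74 list tests passed in all), 68 with the beta-actin covariate (77 in all) and 63 with the Arl2bp and Glo1 covariates (69 in all). Leaving out 1 array gave 1414 (without virgin week 6 replicate A) to 2076 genes between the virgin ages, 105 (without pregnancy day 3 replicate C) to 309 at pregnancy day 3, 836 (without its replicate B) to 1086 at day 14.5, 954 (without lactation day 1 replicate B) to 1791 at lactation day 1, 203 (without lactation day 1 replicate A) to 379 at lactation day 7 and 110 (without virgin week 12 replicate B) to 198 at involution day 20. With the beta-actin ratio as a covariate the counts were 344 between the virgin ages and 531 at pregnancy day 3, and between the virgin ages the median size of the 2278 differences went from 0.95 to 0.58 at a median standard error of 0.302 against 0.294. With the Arl2bp and Glo1 signals as covariates they were 42 at pregnancy day 3, 241 at day 14.5 and 54 at involution day 20, while the median standard error went from 0.294 to 0.359, 0.468 and 0.48 and the median size of the called differences from 1.17 to 1.02, from 1.03 to 0.93 and from 1.52 to 1.55. Elovl5 at pregnancy day 14.5 changed sign with these covariates (0.266, adjusted p = 0.731, against -0.59). The white adipocyte list at involution day 20 had a negative mean both ways, -0.08 and with these covariates -0.599, while its test turned from upward (adjusted p = 0.96) to downward (adjusted p = 0.0426). Apart from these standard errors, the cause of the shifts between settings was not tested. To look for pairing by letter, the deviations of arrays from their time point means were correlated across genes. Between the 2 arrays sharing a letter in a comparison, r ran from -0.1 to 0.074. With the letter as a replicate block 457 named calls held and 4 did not, and the skeletal muscle list at involution day 20 lost its call (adjusted p = 0.0565). Signal over background limits the genes near the floor of 9.4, where a fold is a lower bound.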

Other observations

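Tests chosen only after the result was seen were those of the Glo1 signal and of the genes moving with the Arl2bp level, those of the T cell markers and of the correlation with Igha for the immunoglobulin rise, and that of the Gapdh ratio. Several genes followed courses between the comparisons. Ucp1 had a mean of 136 at virgin week 12, 11.6 at pregnancy day 2 and 52.3 at involution day 4. Rspo1 had means of 61.0 at pregnancy day 3, 215 at day 12.5 and 11.2 at lactation day 1. Glycam1 had means of 14100 at lactation day 7, 4110 at involution day 2 and 155 at day 4. Hp had means of 162, 1620, 2280 and 3610 on the first 4 days of involution, while Orm2 had 3550, 1550, 638 and 110. Pip had means of 22.5 at lactation day 3, 409 at day 7 and 16.5 at involution day 2.

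For the comparisons of 3 arrays with 3, the 10 splits are too few for a share under 0.05, and in each 1 split, the real one, gave as many genes as the real one. The real count and the highest other were 2278 and 0 between the virgin ages, 306 and 0 at pregnancy day 3, 1402 and 1 at day 14.5, 1783 and 87 at lactation day 1, 396 and 33 at lactation day 7, 1969 and 9 at involution day 1, 1832 and 2 at day 4, and 189 and 1 at day 20. For the 18 time points 1 of 100 regroupings, the real one, gave as many genes (6505, highest other 1), so chance is excluded.

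Many genes differed between virgin weeks 12 and 6, and so did the beta-actin ratio, and age stays open as an untested biological explanation. Changes predicted from slopes on that ratio within the other 16 time points correlated with the observed changes across genes at r = 0.70, with median sizes of 0.39 and 0.95 in called genes, so what the beta-actin ratio reads may have contributed. The same r was 0.31 at pregnancy day 14.5 and 0.39 at involution day 20 against virgin week 12, 0.28 at lactation day 1 and 0.24 at involution day 1. The mean Gapdh ratio moved the other way between the virgin ages (2.58 and 3.95) and gave r = -0.13. Week 12 mouse A, at 2.2, lay below every week 6 mouse, and the ratio varied most at pregnancy day 1 (15.2 ± 11.2, SD, n = 3). The direction of the Gapdh shift is thus not resolved, and its test cannot decide on a loss of integrity. Scaling by the authors is argued against as the whole cause, since the lowest count under quantile or median scaling was 1997.

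The Arl2bp signal fell into 2 levels, with a gap of 3.77-fold between neighbouring arrays. Within the time points holding both levels, 54 other genes were called with the Arl2bp level, 11 higher and 43 lower, with a largest log2 rise of 1.49. With the levels permuted within time points, the highest count in 99 draws was 38. A graded share of another tissue stays open, although no array lay between the levels. Of the other genes, 4 were called higher by at least 0.5 times the log2 difference of Arl2bp (2.55). The beta-actin ratio did not differ detectably between the levels (exact permutation p = 0.87). In the same time points Glo1, a gene with a known copy number variant, differed between the levels (exact permutation p = 0.0041, two-sided, 15 arrays, mean log2 difference -1.07). That test was chosen after the result was seen. Glo1 also had the lowest adjusted p of the genes called with the level (limma, 2.2e-07), so the permutation p is not independent support. A candidate explanation is mice of different genetic backgrounds, although the time points where all arrays had the higher Arl2bp level had Glo1 means of 350 at virgin week 6 and 387 at week 12 but 207 at week 10 and 212, 216 and 224 at pregnancy days 1, 2 and 3. No biological explanation named by the design was tested.

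Of 26 immunoglobulin probe sets, in the comparisons of the report, 11 were called higher and 0 lower at virgin week 12 (4.6 higher expected from all genes called), 0 and 1 at pregnancy day 3 (0.66), 1 and 4 at day 14.5 (2.5), 1 and 0 at lactation day 1 (2.7), 15 and 0 at day 7 (0.61), 0 and 0 at involution day 1 (4), 10 and 1 at day 4 (3.5) and 18 and 1 at day 20 (0.31). Remaining lymph node tissue is argued against at involution day 20 against virgin week 12, where the T cell markers had a median log2 change of -0.98 with 7 of 7 below 0 and list means of -0.302, -1.959 and -1.641 in mice A, B and C against a lowest of -0.153 at week 12, but stays open for the rise from lactation day 1 to day 7, where that median was 0.20 with 0 markers called. Signal of 1 transcript shared between related probe sets stays open, since the 17 other probe sets called higher at day 20 followed Igha across the arrays at a median r of 0.90, as they would if plasma cells rose. For the rise to lactation day 7, different genetic backgrounds as read from the Arl2bp level are argued against by Igha. Its lowest signal at lactation day 7 was 5.65 times the highest among the 4 arrays of lactation days 1 and 3 with the lower Arl2bp level. That ratio does not cover day 20, whose arrays were all at the lower level against the higher level at virgin week 12. Nor does it cover a difference in background that the Arl2bp level does not mark. A rise in plasma cells with lactation may explain the pattern too, as a hypothesis found on the same data. The fixed list of B and plasma cell markers did not pass at day 20 (1 of 9 higher, camera adjusted p = 0.6). It mixes markers of both cell types, and its members went apart, Jchain at 1020 against 77.7 and Cd79b at 32.6 against 113. The list therefore cannot decide on plasma cells. Against virgin week 12 the greater age of the day 20 mice cannot be told apart from the cycle.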
